A study of Mus musculus with 6 samples.

How the data were processed

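The samples were pancreatic islets isolated by collagenase digestion from non-pregnant mice (0 dpc) and from mice at 12.5 dpc, 3 arrays of each. Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA with an Affymetrix 3' in vitro transcription kit. The deposited values are intensities on a linear scale, MAS5 signals per the submitters' processing notes, with 1 value per probe set and array. The MAS5 version and its settings are not given in the sources used here, and detection calls were not used here. The 2% trimmed mean was 500.003 on every array, which is how MAS5 scales arrays to a common target. The signals of the TrpnX controls, for a bacterial transcript, ran from 1.1 to 32.3.

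The table held 45101 probe sets, of which 64 AFFX controls were left out of the comparison. Values were taken as log2(signal + 16), where 16 is a pseudocount, so log2 differences are on that scale. The trimmed means were within 5% of each other, so by the rule fixed beforehand no further normalization was applied. Probe sets in the top 60% by mean log2 value over all 6 arrays were tested, which left 27022 and corresponds to a signal of about 50.5.

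Gene names came from the platform annotation. It gave 34958 probe sets a single symbol and 932 several, and it did not name 9211, which are unnamed here and not without a gene. Symbols were checked through Entrez identifiers in the RefSeq gene table of the mouse, in which 34754 were found and 0 symbols changed. Probe sets with several symbols were never named. Of those past the threshold, 230 had no single symbol. A gene was represented by its probe set with the highest mean log2 value. Among 6088 genes with several tested probe sets, 4 had probe sets called in both directions, 1 of them (Ddc) named in the text.

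The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of variance on signal), 2-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no covariate. Errors of log2 differences are limma's standard errors and errors of signals are standard deviations. The fit left 4 residual degrees of freedom. A 2-fold rule meant an absolute log2 difference of at least 1. At an unadjusted p under 0.05 there were 6190 probe sets, where chance alone would give 1351.

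Of 26 gene lists fixed with 495 genes, 449 genes were named on the array and 405 tested. Lists with at least 3 tested genes were compared with all other genes by camera (preset correlation 0.01; also with an estimated correlation), 2-sided, adjusted over 25 lists. The gene Atf3 is in 2 lists. The lists, the design, the settings tried and the rule for naming genes were set before the data were examined. That rule took the 12 largest rises and 12 largest falls past the threshold in which the groups did not overlap, up to 4 genes with the smallest p from each list, and genes of prior interest in serotonin synthesis, lactogen signalling, division and islet hormones. Of the probe sets tested, 27.7% had groups that did not overlap, where chance gives 10%.

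The fit was tested on simulated data made from this comparison, with 27022 probe sets, 20 draws and 200 probe sets changed in each. With each probe set's spread drawn from the fitted prior, 25.2%, 63.2%, 90.9% and 99.3% of the probe sets changed by 0.5, 1, 2 and 4 on the log2 scale were recovered, and 5.54% of the calls were false. With the fitted spread of each probe set, 37.6%, 76.1%, 96.2% and 99.9% were recovered and 8.2% of the calls were false. The prior version was added after the other had given more false calls than the threshold. In both, all 20 shifted sets of 25 genes were called and 0 of 400 unchanged sets. The simulated errors were independent between probe sets, so these sets had no correlation between genes. The fixed lists do, with an estimated correlation of 0.92 for the acinar and 0.34 for the mitosis list. The simulation therefore does not measure how often camera calls such lists falsely. Both kinds of spread came from the fit with the variance trend and were fitted again with that trend. The shares of false calls thus take the trend as given and do not test it.

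Alternatives were pseudocounts of 1 and 64, quantile normalization, centring on each array's median, no filter and a top 40% filter, eBayes without the trend or robust, array weights, the replicate number as a block, each array left out, 1 mean value per gene and, for lists, an estimated correlation. The median of the acinar markers on each array was added as a covariate after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.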

Results

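Gene expression was measured in pancreatic islets, the clusters of hormone-secreting endocrine cells that lie within the exocrine pancreas. Islets came from non-pregnant mice (0 days post coitum, dpc; 3 arrays) and from mice at 12.5 dpc of pregnancy (3 arrays), and the study asked what drives islet cells to divide in pregnancy. Each array gave a MAS5 signal, a background-corrected and scaled intensity, for 45101 probe sets. Every array had the same 2% trimmed mean signal of 500.003, and the median signals lay between 86.1 and 100.3. The ratio of the 3' to the 5' control probe set, a measure of RNA integrity, was 0.669 to 0.711 in non-pregnant and 0.687 to 0.725 in pregnant arrays for Gapdh. For beta actin it was 1.56 to 1.63 in non-pregnant and 1.63 to 1.67 in pregnant arrays, without overlap, which chance gives in 10% of such comparisons. Nothing in the labels says that the 3 arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

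Tph1 and Tph2, the enzymes that catalyse the rate-limiting step of serotonin synthesis, were among the 4 genes with the largest rises in pregnancy. The mean signal of Tph1 was 53.2 ± 26.2 (SD, n = 3) in non-pregnant and 4749 ± 312 (n = 3) in pregnant islets, a ratio of 89.2 and a log2 difference of 6.17 ± 0.21 (SE; limma adjusted p = 7.1e-09). Cldn8, a tight junction claudin, rose from 133.6 ± 19.2 to 9045 ± 541 (log2 difference 5.93 ± 0.10, adjusted p = 7.8e-12). Sftpd, the collectin surfactant protein D, rose from 69.5 ± 7.86 to 2902 ± 579 (5.08 ± 0.15, adjusted p = 2.2e-09), and Tph2 from 73.5 ± 33.0 to 1302 ± 229.6 (3.92 ± 0.22, adjusted p = 7.9e-07). Fmo1, a flavin-containing monooxygenase, was already bright without pregnancy and rose from 1541 ± 75.3 to 17541 ± 245 (3.50 ± 0.06, adjusted p = 7.8e-12).

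The other largest rises, ordered by log2 difference, were those of Gbp8, a guanylate-binding protein (3.78 ± 0.21), Neb, the actin-binding protein nebulin (3.26 ± 0.24), Esr1, the estrogen receptor alpha (3.15 ± 0.29), Tnfrsf11b, the decoy receptor osteoprotegerin (2.90 ± 0.17), Slc26a3, an anion exchanger (2.83 ± 0.40), Crispld2 (2.80 ± 0.18) and the matrix protein Matn2 (2.77 ± 0.09). Their adjusted p-values lay between 6.3e-09 for Matn2 and 9.5e-04 for Slc26a3. The non-pregnant signals of Esr1 (15.4 ± 9.58), Slc26a3 (17.6 ± 18.7) and Neb (25.2 ± 6.52) were within the 1.1 to 32.3 spanned by control probe sets for a bacterial transcript. The log2 values include a pseudocount of 16, which understates the change of such dim genes. With a pseudocount of 64 Esr1 had 2.01 and Slc26a3 1.74, and with a pseudocount of 1 Esr1 had 4.11. For Slc26a3 a pseudocount of 1 made the other of its 2 tested probe sets the representative. Its 1.58 there is thus no measure of the pseudocount.

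**Figure D1:**
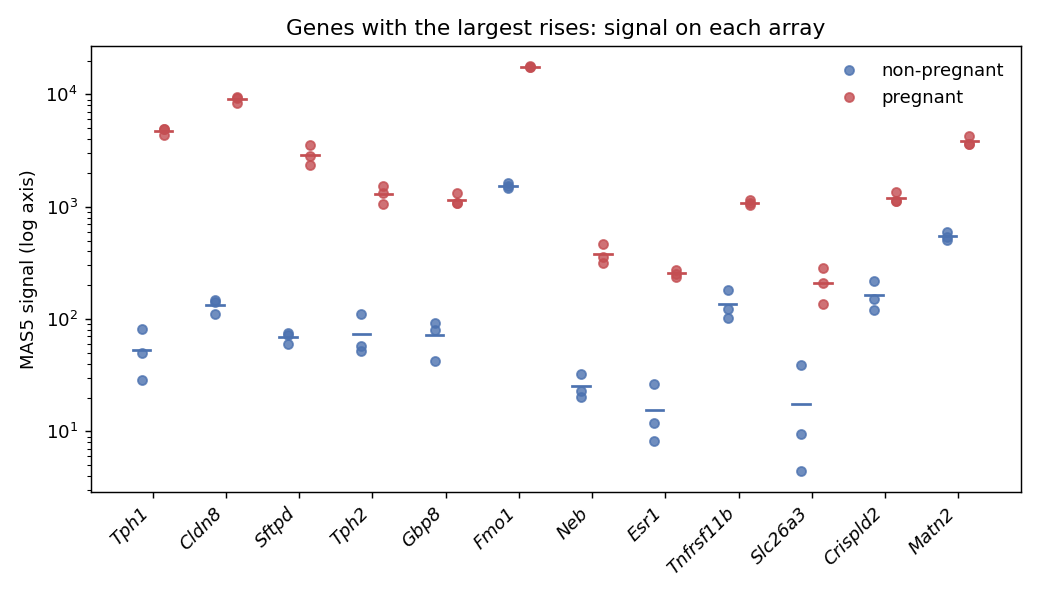
MAS5 signal (log axis) of the 12 genes with the largest rises, 1 point per array, with non-pregnant arrays in blue, pregnant arrays in red and a short line at each group mean (n = 3 per group). For each gene all 3 pregnant arrays lie above all 3 non-pregnant arrays, as the naming rule requires, and Tph1 goes from a mean of 53.2 to 4749.

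The largest falls were smaller than the largest rises, and several of the genes are made by exocrine acinar cells. Gp2, the major glycoprotein of zymogen granule membranes, went from 2184 ± 1112 to 549.8 ± 225.8 (log2 difference -1.87 ± 0.36, adjusted p = 0.0067). Pnliprp2 (-1.74 ± 0.30), Sycn (-1.60 ± 0.31) and Pnliprp1 (-1.58 ± 0.30), which encode 2 lipase-related proteins and the zymogen granule protein syncollin, fell too, as did the pancreatic protein disulfide isomerase Pdia2 (-1.75 ± 0.37), the kallikrein Klk1 (-1.61 ± 0.30) and the trefoil peptide Tff2 (-1.80 ± 0.35). Scd1, a fatty acid desaturase, fell by 1.59 ± 0.20 (adjusted p = 4.4e-04). Aldh1a1 (-1.73 ± 0.39), Hamp2 (-1.67 ± 0.36), Kcnj4 (-1.63 ± 0.38) and Asb9 (-1.58 ± 0.35) complete the 12. Their adjusted p-values were 0.015, 0.013, 0.020 and 0.014. Without 1 array these rose to as much as 0.070 for Aldh1a1 and 0.066 for Asb9 (both without non-pregnant replicate 2), 0.066 for Hamp2 (without non-pregnant replicate 3) and 0.084 for Kcnj4 (without non-pregnant replicate 1), which did not pass with no filter either (0.059). For Pdia2 the adjusted p was 0.010, and 0.055 without pregnant replicate 1. With robust eBayes, Gp2, Tff2, Pdia2, Pnliprp2, Klk1, Sycn and Pnliprp1 did not pass, at adjusted p-values of 0.13 for Pnliprp2 to 0.19 for Pdia2. Without the trend in the variance model, Scd1 alone of the 12 passed, and likewise with the median acinar marker level of each array as a covariate, chosen after the data were seen. With that covariate Gp2 had -0.13 and Pdia2 -0.01, while Scd1 had -2.30. Gp2, Pnliprp2, Sycn and Pnliprp1 are among the markers whose median it is, so their lost calls follow from how it was built. Pdia2 and Scd1 are not part of the covariate. Aldh1a1 (-1.71), Hamp2 (-1.76), Kcnj4 (-1.97) and Asb9 (-2.19) kept their size with it but did not pass. With a pseudocount of 64 Aldh1a1 had -1.06, Hamp2 -1.07 and Kcnj4 -1.01, and with its probe sets averaged Klk1 had -0.89.

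Of 27022 probe sets tested, 2587 (9.57%) passed an adjusted p of 0.05 in limma, 1294 higher and 1293 lower in pregnancy. A further size rule of 2-fold left 197 higher and 114 lower. The even split depends on the scale: with each array centred on its median, 1430 were higher and 583 lower, and without the trend in the variance model 393 were higher and 210 lower. With the acinar covariate 362 were higher and 179 lower. The count was 1488 without pregnant replicate 1 and 1578 without pregnant replicate 2, and 812 and 858 were lower without non-pregnant replicate 2 and without pregnant replicate 3. By gene, 788 rose and 748 fell of 12914. On the first principal component, which held 36.8% of the variance, the 3 pregnant arrays lay between 25.1 and 31.4 and the non-pregnant arrays between -30.2 and -26.4.

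In the serotonin synthesis list, 3 of 11 genes tested rose and 0 fell, also when adjusted over the list alone. These were Tph1, Tph2 and Ddc, the decarboxylase that makes serotonin from 5-hydroxytryptophan, whose signal went from 15384 ± 399 to 19748 ± 606 (log2 difference 0.36 ± 0.05, adjusted p = 7.8e-04). A second, dimmer Ddc probe set was lower in pregnancy (-0.53 ± 0.13, adjusted p = 0.023). The other 8 genes did not pass, among them Spr, which supplies the cofactor of the hydroxylases (-0.36 ± 0.15, adjusted p = 0.16). The list had a median of 0.0014 and a mean of 0.93, and was called higher by camera (adjusted p = 0.018; adjusted p = 0.34 with an estimated correlation). With quantile normalization its median was -0.02 (adjusted p = 0.067), and with each gene's probe sets averaged the adjusted p was 0.21. Its median was -0.01 to 0.07 with any 1 array left out. Among 5 serotonin receptor genes tested, 0 rose and 1 fell, and the list was not called (adjusted p = 0.30). The ion channel receptor Htr3a fell by 0.84 ± 0.19 (adjusted p = 0.016, and 0.067 without pregnant replicate 1), while Htr1d had a log2 difference of -0.41 ± 0.37 (adjusted p = 0.58; -0.75 to -0.09 with any 1 array left out). Ddc and Htr3a did not pass without the variance trend or with the acinar covariate, where they had 0.38 and -0.68. Htr2b was too dim to be tested, with mean signals of 3.53 ± 1.27 and 6.70 ± 4.69.

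Of 12 genes of lactogen signalling tested, 2 rose and 2 fell. Cish and Socs2, which STAT5 induces downstream of the prolactin and growth hormone receptors, went from 2131 ± 472 to 5455 ± 80.3 (log2 difference 1.37 ± 0.12, adjusted p = 1.9e-05) and from 4711 ± 372 to 8815 ± 121.5 (0.90 ± 0.07, adjusted p = 5.5e-06). Of 5 Socs2 probe sets 3 were higher, and their average had 0.53 (adjusted p = 0.0051). The growth hormone receptor Ghr fell by 0.36 ± 0.06 and the kinase Pim3 by 0.42 ± 0.06 (adjusted p = 0.0029 and 0.0011), but neither passed without the variance trend (0.097 and 0.058) and Ghr did not with the acinar covariate (-0.42, adjusted p = 0.082). The other 8 did not pass, and adjusted over the list alone 2 rose and 3 fell. With a median of -0.15 and a mean of 0.01, the list as a whole was not called (adjusted p = 0.61). Its median was -0.24 without pregnant replicate 2, -0.08 with median centring and -0.10 with the acinar covariate.

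Genes of cell division were higher in pregnancy. In the mitosis list 24 of 36 genes rose and 0 fell (32 rose adjusted over the list alone), with a median log2 difference of 1.09 (camera adjusted p = 1.4e-20; adjusted p = 0.34 with an estimated correlation). The proliferation marker Mki67 went from 204.4 ± 27.1 to 675 ± 110.4 (1.64 ± 0.15, adjusted p = 3.7e-05) and the mitotic kinase Cdk1 from 137.6 ± 5.0 to 499 ± 124 (1.72 ± 0.18, adjusted p = 1.2e-04). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, rose by 1.55 ± 0.14 and the kinase Pbk by 1.56 ± 0.17. Foxm1, a transcription factor of mitotic genes, did not pass (0.20 ± 0.22, adjusted p = 0.66; 0.03 without non-pregnant replicate 1). In the DNA replication list 16 of 27 genes rose and 0 fell (22 rose adjusted over the list alone), with a median of 0.59 (camera adjusted p = 1.1e-13; adjusted p = 0.13 with an estimated correlation). Examples were the replication factor Gins2 (1.68 ± 0.23), the helicase subunit Mcm5 (1.23 ± 0.16), the ribonucleotide reductase subunit Rrm2 (1.18 ± 0.13) and the sliding clamp Pcna (0.54 ± 0.06). Acinar markers moved the other way, and with their median as a covariate 9 mitosis and 5 replication genes rose, and camera still called both lists. Without the variance trend 14 and 7 rose.

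Among 20 G1 cyclins and cell cycle inhibitors, 3 rose and 1 fell (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.20). Ccnd1, cyclin D1, rose by 0.39 ± 0.08 (adjusted p = 0.0070), and the inhibitor Cdkn1a fell by 0.62 ± 0.11 (adjusted p = 0.0043). The transcription factor E2f1 rose by 0.78 ± 0.17 (adjusted p = 0.013, and 0.054 without pregnant replicate 2). Men1, the tumour suppressor menin, was 0.41 ± 0.11 higher (adjusted p = 0.030). This held in 1 of its 3 probe sets, and the adjusted p was 0.31 with the probe sets averaged and 0.11 without pregnant replicate 2. Without the variance trend 0 of the list rose or fell (Ccnd1 at an adjusted p of 0.12, Cdkn1a at 0.077), and E2f1 (0.31) and Men1 (0.59) did not pass with the acinar covariate either. With that covariate Ccnd1 had 0.59 and Cdkn1a -0.98, and both passed. Ccnd2, cyclin D2, did not pass in its brightest probe set (-0.10 ± 0.05, adjusted p = 0.24), though 3 of its 7 probe sets were lower.

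Beta cell genes were balanced around no change. Of 24 tested, 2 rose and 3 fell (2 and 4 adjusted over the list alone), the median log2 difference was 0.002, and the list was not called (adjusted p = 0.64). With median centring 2 rose and 0 fell (median 0.08), and with the acinar covariate 2 rose and 0 fell (median -0.02). The prohormone convertase Pcsk1 rose from 4609 ± 406 to 8810 ± 217 (0.94 ± 0.07, adjusted p = 6.0e-06) and the granule protein Chgb from 29759 ± 902 to 43789 ± 950 (0.56 ± 0.05, adjusted p = 1.7e-05). The glucose transporter Slc2a2 fell by 0.25 ± 0.05 and the zinc transporter Slc30a8 by 0.29 ± 0.06 (adjusted p = 0.0063 and 0.010). Neither passed with each array centred on its median (adjusted p = 0.24 and 0.13), and Slc30a8 had 0.055 without pregnant replicate 2. Ins2 had a log2 difference of 0.13 ± 0.08 (adjusted p = 0.40) and the transcription factor Pdx1 0.05 ± 0.07 (adjusted p = 0.74). In the list of other islet hormones and their cells, 0 of 10 rose and 2 fell (3 adjusted over the list alone), with a median of -0.17. Camera called the list lower (adjusted p = 0.0099; adjusted p = 0.34 with an estimated correlation, and 0.15 with quantile normalization). Ghrl, ghrelin, fell from 750.2 ± 18.3 to 339.7 ± 97.0 (-1.14 ± 0.16, adjusted p = 9.8e-04). The alpha cell factor Irx1 had -0.40 ± 0.11 (adjusted p = 0.033, and 0.11 without pregnant replicate 2), glucagon, Gcg, had -0.04 ± 0.05 and somatostatin, Sst, -0.04 ± 0.04 (adjusted p = 0.66 and 0.70). The mean signals of Gcg (48010 non-pregnant, 46589 pregnant) and Sst (47162, 45997) were near the highest signal of an array, 51107 to 64109. A change of such bright genes could be missed. The list median was -0.09 with median centring, and Irx1 did not pass with that or with quantile normalization. Slc2a2, Slc30a8 and Irx1 did not pass without the variance trend, and neither these 3 nor Ghrl passed with the acinar covariate. With it Slc2a2 had -0.24, Slc30a8 -0.36, Irx1 -0.56 and Ghrl -0.79, so these lost calls alone are no support for acinar share as their source. Ghrl fell less with the covariate than without it, so a part of its fall stays open.

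Markers of acinar cells, the enzyme-secreting exocrine cells around islets, were lower in pregnancy. Of 24 tested, 20 fell and 1 rose (22 and 1 adjusted over the list alone), with a median log2 difference of -1.15 (camera adjusted p = 1.7e-10; adjusted p = 0.43 with an estimated correlation). Without pregnant replicate 1 only 7 fell, with robust eBayes 1 and without the variance trend 0. Camera still called the list without pregnant replicate 1. It used a variance trend in every setting, so its call is no check on the robust or untrended variance model. The elastase Cela1, the brightest of those named, went from 36715 ± 9420 to 17102 ± 3101 (-1.08 ± 0.17). The median of the list, centred per gene, was 0.94, -0.13 and 0.96 on non-pregnant replicates 1, 2 and 3 and -0.89, -0.62 and -0.23 on pregnant replicates 1, 2 and 3. Bhlha15, a transcription factor of secretory cells, was the 1 member that rose, from 1149 ± 136 to 2602 ± 36.3 (1.18 ± 0.09, adjusted p = 8.6e-06). The REG family of secreted lectins was not called (5 tested, 0 rose, 1 fell, adjusted p = 0.23), though 2 fell adjusted over the list alone. Reg3d had -1.08 ± 0.30 (adjusted p = 0.040, and 0.16 without pregnant replicate 1) and Reg1 -0.84 ± 0.28 (adjusted p = 0.091). Neither Cela1 nor Reg3d passed with robust eBayes or without the variance trend, and Reg3d did not with quantile normalization or no filter. Without pregnant replicate 3 and without non-pregnant replicate 2, camera called the REG list lower (adjusted p = 0.0045 and 0.035). With the acinar covariate its median was 0.53 (adjusted p = 0.028).

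**Figure D2:**
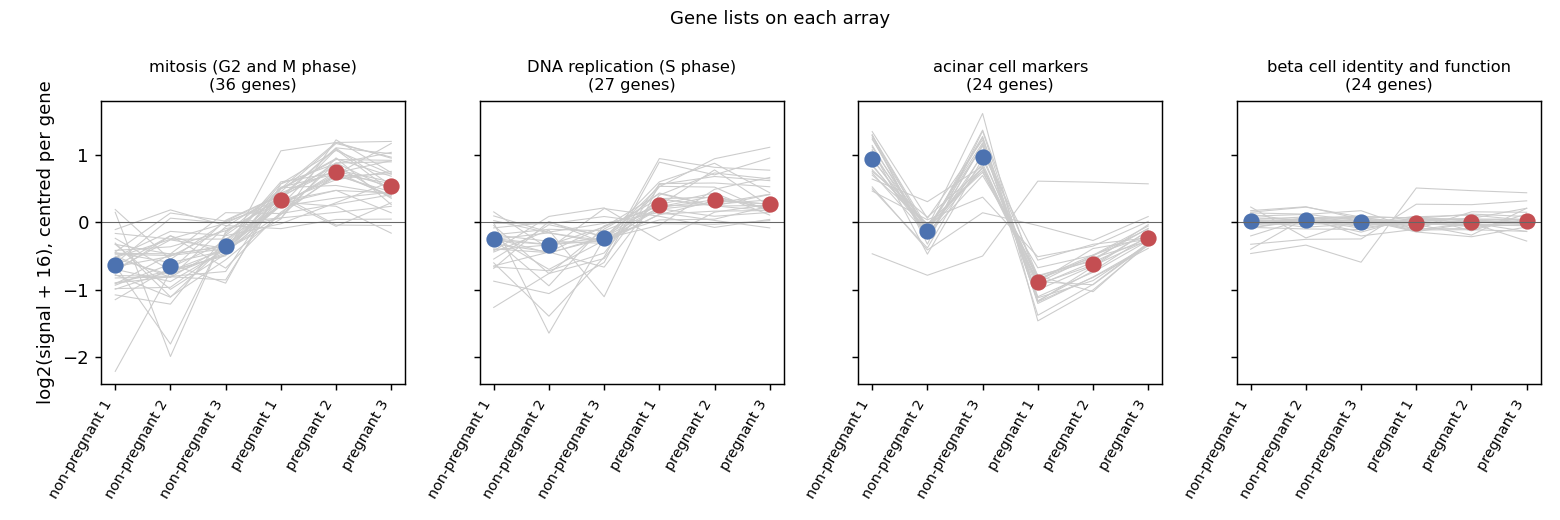
Log2(signal + 16), centred per gene, of the genes in 4 lists on each of the 6 arrays. Grey lines are single genes, and large points are list medians (blue, non-pregnant; red, pregnant). The mitosis and DNA replication medians are above 0 on all 3 pregnant arrays, the acinar median is 0.94, -0.13 and 0.96 on the non-pregnant arrays and -0.89, -0.62 and -0.23 on the pregnant arrays, and the beta cell median lies between -0.02 and 0.03.

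The acinar median thus went with the group, so other lists were also tested with it as a covariate. Stellate cell and fibroblast markers had a median of -0.28, with 1 of 18 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.43 with an estimated correlation). The matrix proteoglycan Dcn fell from 1341 ± 57.2 to 587.6 ± 148 (-1.20 ± 0.14, adjusted p = 2.8e-04), the collagen genes Col3a1 and Col1a2 fell by 0.75 ± 0.11 and 0.73 ± 0.11, and Col6a3 rose by 0.67 ± 0.09. Endothelial markers had a median of -0.19, and only 1 of 16 fell, the VEGF receptor Flt1 (-0.47 ± 0.10, adjusted p = 0.010). Camera called that list lower (adjusted p = 0.029; adjusted p = 0.46 with an estimated correlation), but not without pregnant replicate 1 (0.21), without non-pregnant replicate 3 (0.099) or with quantile normalization (0.052). With the acinar covariate the adjusted p was 0.48 for the stellate list, 0.48 for the endothelial list and 0.072 for the other islet hormones. Dcn (-0.84, adjusted p = 0.089), Col3a1 (-0.58, 0.15), Col1a2 (-0.60, 0.15) and Flt1 (-0.59, 0.13) did not pass with it either, and 0 stellate genes fell. The stellate median was still -0.24, so the lost calls alone are no support for acinar share as the source of these falls. Dcn, Col3a1 and Col1a2 fell less with the covariate and Flt1 fell more, so a part of the stellate falls stays open. Col3a1 and Flt1 did not pass without the variance trend. The endothelial median was -0.11 with median centring.

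None of the lists tested for other cell types was called by camera. Of 10 duct markers 1 rose, the keratin Krt18 (0.33 ± 0.05), and 3 fell, the tetraspanin Tspan8 (-0.45 ± 0.11, adjusted p = 0.024), the claudin Cldn4 (-0.45 ± 0.07, adjusted p = 0.0012) and the keratin Krt7 (-0.27 ± 0.06, adjusted p = 0.016). Adjusted over the list alone these were 2 and 3 (list adjusted p = 0.69). Without pregnant replicate 1 (Krt7 0.080, Tspan8 0.11) and with median centring only Cldn4 fell, and 0 of the list rose or fell without the variance trend or with the acinar covariate. With the covariate Tspan8 had -0.12, Cldn4 -0.48, Krt7 -0.25 and Krt18 0.25. Of 14 macrophage markers 1 rose, also when adjusted over the list alone. This was C1qa, which went from 3505 ± 352 to 7300 ± 613 (1.06 ± 0.08, adjusted p = 1.1e-05), while C1qb, a chain of the same complement protein, had -0.17 ± 0.11 (adjusted p = 0.38; list adjusted p = 0.73). Of 7 Schwann cell and neuronal markers the neurotrophin receptor Ngfr rose by 1.61 ± 0.20 (adjusted p = 3.3e-04). The neuronal filament gene Prph had -1.18 ± 0.29 (adjusted p = 0.024, and 0.081 without non-pregnant replicate 1), and the list was not called (adjusted p = 0.56), with 1 higher and 1 lower adjusted over the list alone too. Of 3 adipocyte markers 1 passed, also over the list alone, Pparg (0.93 ± 0.25, adjusted p = 0.035, and 0.14 without pregnant replicate 2; list adjusted p = 0.20). None of 6 lymphocyte markers passed in limma on either adjustment, and 1 had an unadjusted p under 0.05. That list had a median of -0.15 and a mean of -0.02, and camera's direction was up (adjusted p = 0.98). Its median was 0.0089 without non-pregnant replicate 2 and -0.08 with median centring. Prph and Pparg did not pass without the variance trend or with no filter, Prph did not with robust eBayes, and neither these 2 nor Ngfr passed with the acinar covariate (-0.33 for Prph, 1.16 for Pparg and 1.19 for Ngfr). Prph had -0.75 without pregnant replicate 1. Of 7 erythroid markers 4 had a named probe set, and 0 of those were bright enough to be tested.

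In the list of the unfolded protein response, the set of chaperones and sensors that endoplasmic reticulum load induces, 10 of 25 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.15 (camera adjusted p = 2.6e-07; adjusted p = 0.34 with an estimated correlation). The cochaperone Dnajb11 went from 1947 ± 268 to 3304 ± 262 (0.76 ± 0.10, adjusted p = 4.2e-04), and Dnajc3 and Sdf2l1 rose by 0.43 ± 0.05 and 0.51 ± 0.06. The stress sensor Ern1 rose by 0.89 ± 0.07 in its brightest probe set and had an adjusted p of 0.090 with its 5 probe sets averaged. Without the variance trend 2 of the list rose, and with the acinar covariate 3. Dnajc3 did not pass in either (0.35 with the covariate) and Sdf2l1 did not without the trend. The list median was 0.22 with median centring. Of 22 genes of amino acid synthesis, transport and tRNA charging, 6 rose and 0 fell (7 and 1 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 2.9e-04; adjusted p = 0.43 with an estimated correlation). Those named charge tRNAs: Nars (0.39 ± 0.07), Gars (0.32 ± 0.06), Lars (0.31 ± 0.07, adjusted p = 0.053 without pregnant replicate 1) and Eprs (0.29 ± 0.07, adjusted p = 0.099 without pregnant replicate 3, and 0.16 at an adjusted p of 0.27 with its probe sets averaged). With the acinar covariate its median was -0.0061 (adjusted p = 0.72), and without non-pregnant replicate 2 it was 0.24. Without pregnant replicate 1, and likewise without pregnant replicate 3, 2 of its genes rose, and 0 rose without the variance trend or with the acinar covariate (Nars 0.23, Gars 0.17, Lars 0.33, Eprs 0.32).

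Of 23 oxidative phosphorylation genes 4 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0021; adjusted p = 0.55 with an estimated correlation, and 0.052 with quantile normalization). The largest rises were those of Ndufa4, which went from 5685 ± 441 to 10349 ± 598 (0.86 ± 0.07, adjusted p = 1.1e-05), and Cox5a (0.44 ± 0.06), both respiratory chain proteins. The other 2, Cycs (0.29 ± 0.07) and Cox6c (0.17 ± 0.05), had adjusted p-values of 0.020 and 0.045, and 0.082 and 0.18 without pregnant replicate 1. Of the list, 9 genes rose without non-pregnant replicate 1 (median 0.14), and 2 without non-pregnant replicate 2 or 3 or without pregnant replicate 1 or 2. Without the variance trend or with the acinar covariate (median 0.15) 1 rose, Ndufa4, and with no filter 2. With the covariate Cox5a had 0.44, Cycs 0.40 and Cox6c 0.18. With median centring the list median was 0.14. Among 16 glycolysis genes 0 rose and 3 fell (2 and 3 adjusted over the list alone), without a call for the list (adjusted p = 0.64). Of the list, 2 rose and 1 fell without non-pregnant replicate 1, and 1 fell without non-pregnant replicate 3 or pregnant replicate 1, with median centring or with the acinar covariate. Both lactate dehydrogenase genes fell, Ldhb by 0.63 ± 0.09 (adjusted p = 7.2e-04) and Ldha by 0.58 ± 0.13 (adjusted p = 0.016, and 0.066 without non-pregnant replicate 3). The hexokinase Hk2 had -0.83 ± 0.24 (adjusted p = 0.049, and 0.065 to 0.15 with any 1 array left out, highest without non-pregnant replicate 2). Neither Ldha nor Hk2 passed with median centring (0.055 and 0.077) or the acinar covariate (-0.25 and -0.92). Ldha did not without the variance trend, nor Hk2 with a pseudocount of 1, quantile normalization or no filter. Of 18 cholesterol synthesis genes 2 rose and 0 fell (2 and 1 adjusted over the list alone), the reductase Dhcr7 from 407.8 ± 134 to 1110 ± 126 (1.45 ± 0.18, adjusted p = 3.8e-04) and the epoxidase Sqle by 0.60 ± 0.07 (adjusted p = 3.3e-04). The list had a median of -0.04, a mean of 0.08 and no call (adjusted p = 0.48). The median was 0.04 without non-pregnant replicate 1, 0.02 without pregnant replicate 3 and 0.04 with median centring.

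Immediate early and handling stress genes, which tissue dissociation also induces, were lower in pregnancy. Of 19 tested 9 fell and 0 rose (12 and 1 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 5.6e-06; adjusted p = 0.43 with an estimated correlation). The matricellular gene Ccn1 fell by 0.51 ± 0.07 (adjusted p = 0.0012), Fosb by 0.43 ± 0.08 and Ier3 by 0.46 ± 0.09. The heat shock gene Hspa1a had -0.25 ± 0.05 (adjusted p = 0.014, 0.071 without pregnant replicate 2 and 0.29 with median centring). Fewer of the list fell without pregnant replicate 3 (3 genes), pregnant replicate 1 (4) or non-pregnant replicate 2 (5), with median centring (3) or with no filter (5), and 0 without the variance trend or with the acinar covariate. With that covariate the median was -0.31, and camera still called the list (adjusted p = 1.7e-07).

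Of 22 growth factors and their receptors, 2 rose and 3 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.20). Tnfrsf11b went from 135.5 ± 40.9 to 1089 ± 63.2, Igf2 fell by 0.93 ± 0.19 (adjusted p = 0.0079) and Hbegf by 0.53 ± 0.09 (adjusted p = 0.0031). Epidermal growth factor, Egf, had 0.35 ± 0.08 (adjusted p = 0.021, and 0.082 without pregnant replicate 1). Hbegf and Egf did not pass without the variance trend, and neither these 2 nor Igf2 passed with the acinar covariate, at similar values (Hbegf -0.46, Egf 0.32, Igf2 -1.07). Of 12 interferon response genes 1 passed (1 higher and 1 lower adjusted over the list alone), Gbp3, with 0.60 ± 0.17 (adjusted p = 0.042, and 0.058 to 0.13 with any 1 array left out, highest without pregnant replicate 3), which did not pass with no filter or with the acinar covariate (0.72). That list had a median of -0.07 and a mean of -0.0011, and camera's direction was up without a call (adjusted p = 0.91). The median went from -0.16 (without non-pregnant replicate 3) to 0.0092 (without pregnant replicate 3), and was 0.0044 with median centring. In all, camera called 11 of 25 lists tested with its preset correlation, 6 higher and 5 lower. With an estimated correlation 0 were called, and 3 had an unadjusted p under 0.05.

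**Figure D3:**
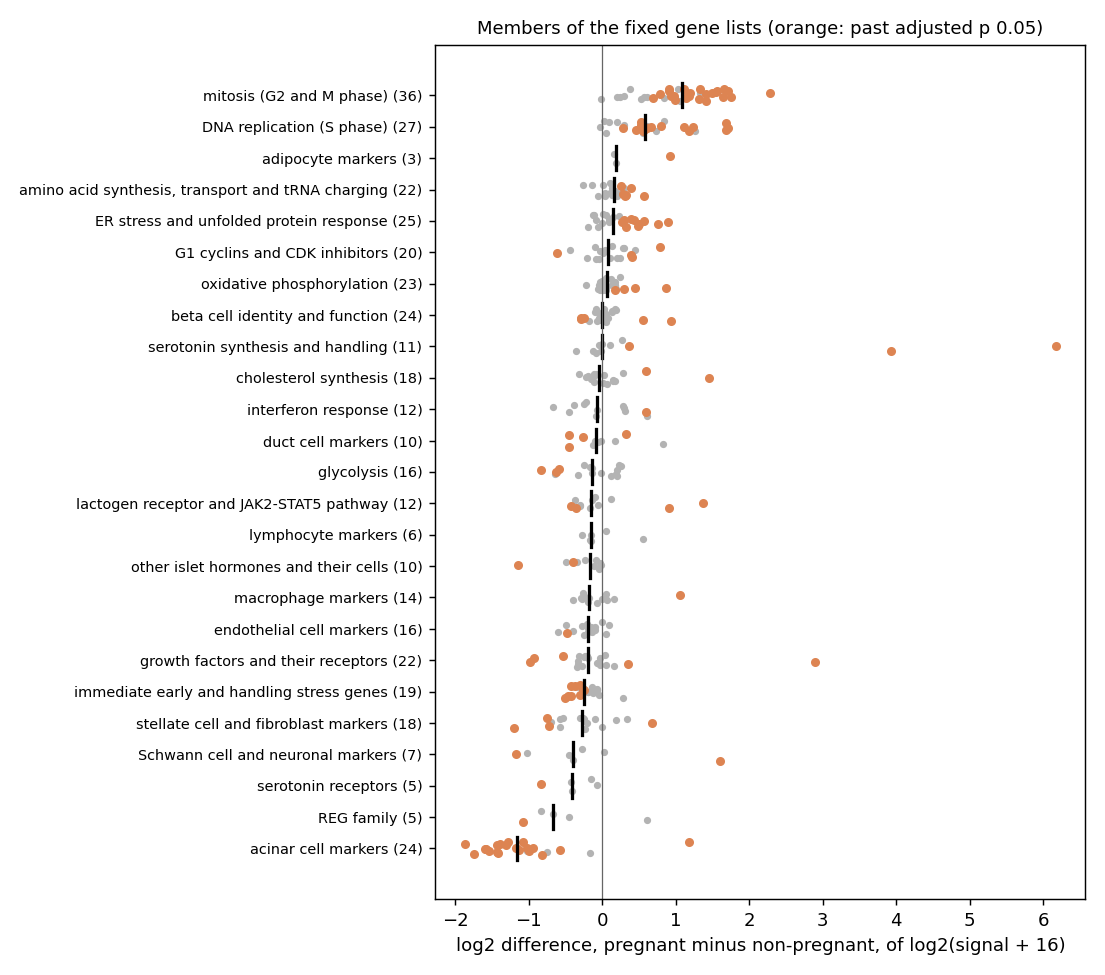
Log2 difference, pregnant minus non-pregnant, of log2(signal + 16) for each gene of the 25 lists tested, with the number of genes in parentheses. Orange points passed an adjusted p of 0.05 in limma, grey points did not, and black bars are list medians, which run from -1.15 for the acinar markers to 1.09 for the mitosis genes.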

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

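The control probe sets had no part in the comparison of the groups, and the test of them was not among those planned. Among them, the 3' control probe set for mouse pyruvate carboxylase, an enzyme that refills the citric acid cycle and is abundant in beta cells, was higher on the pregnant arrays (979 ± 44.4 against 1359 ± 60.6, SD, n = 3 each). Its log2 difference was 0.47 ± 0.08 (limma adjusted p = 0.0037). The 3 other control probe sets for it, dimmer, did not pass (0.36, 0.86 and 0.29, adjusted p = 0.46, 0.26 and 0.34). The probe set annotated to the gene, Pcx, had a log2 difference of 0.27 ± 0.08 (adjusted p = 0.047). Over 42 bacterial and phage control probe sets with a mean signal over 100 the median log2 difference was 0.02.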

How the results depend on the processing

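The acinar covariate was chosen after the data were seen and all other settings before. The count of 2587 was 603 (393 higher, 210 lower, 189 at least 2-fold) for eBayes without the trend, and 583 were lower with median centring. The 2-fold count of 311 was 197 with a pseudocount of 64 and 194 with the top 40% filter, where fewer probe sets enter. Without 1 array, 1488 to 2247 passed, 811 to 1271 higher and 677 to 976 lower, all lowest without pregnant replicate 1; fewer samples lower such counts. The REG median was -1.13 to -0.16 and the endothelial median -0.19 became -0.24 to -0.14. With the replicate number as a block (replicate block) 2356 passed and no list call changed, while Hk2, Gbp3 and Irx1 lost and Reg1 gained a call. Arrays with the same number did not deviate together (r = -0.03, -0.07 and 0.03 across probe sets), so they share only a number. With the acinar covariate, which itself largely follows the group and so leaves less to test, 541 passed (362 higher, 179 lower), 476 of them among the 2587, and 50 of 89 named calls were lost; the cause was not tested. Its medians were -0.0011 for acinar genes, with camera's direction reversed, 0.53 for REG, -0.13 for other hormones, -0.12 for endothelial, -0.24 for stellate and -0.0061 for amino acid genes, and Reg3d and Reg1 turned to 0.12 and 0.53. The acinar value follows from how the covariate was built, since the acinar genes set it. Quantile normalization ended the calls of serotonin synthesis (-0.024), other hormones (-0.13), endothelial (-0.18) and oxidative phosphorylation genes (0.053). With probe sets averaged, serotonin synthesis (0.0014) lost its call and Ddc turned to -0.083, since its probe sets disagree. Camera with an estimated correlation ended all 11 list calls and left medians as they were, at 0.0014 (serotonin synthesis), 0.59 (DNA replication), 1.09 (mitosis), -0.17 (other hormones), -1.15 (acinar), -0.19 (endothelial), -0.28 (stellate), 0.15 (unfolded protein response), 0.16 (amino acid), 0.068 (oxidative phosphorylation) and -0.25 (immediate early). The serotonin list lost its call at an estimated correlation of -0.03, below the preset 0.01. A higher correlation between genes is thus not the reason for that loss. Of 89 named calls, 65 held without any 1 array and 48 were lost without the trend; pseudocount 64 and array weights ended 0. With the top 40% filter 23 lists had enough genes, and all 23 kept their side of the threshold. A signal near that of the bacterial controls limits the folds of dim genes. The causes of these changes were not tested.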

Other observations

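The tests of acinar share and scaling, of the cell cycle explanations and of the added lists were chosen after the result was seen, while the splits and the tests of the lower calls and of acinar regulation were set before theirs. Ivd, Ehhadh and Birc5 were named after their values were seen. Ivd, isovaleryl-CoA dehydrogenase of leucine breakdown, was higher in 2 probe sets (log2 difference 2.33 ± 0.08 and 1.74 ± 0.07, limma adjusted p = 6.3e-09 and 2.7e-08). Ehhadh, a peroxisomal enzyme of fatty acid oxidation, had 2.08 ± 0.10 (adjusted p = 2.6e-07), and Birc5, the mitotic regulator survivin, had 2.29 ± 0.37 (adjusted p = 0.0021).

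Lists were then written for 4 such genes or pairs, without the genes that prompted them, as hypotheses. Genes of branched-chain amino acid breakdown, prompted by Ivd, may be higher as a group, with a median of 0.16 and 2 of 20 risen, Bckdhb and Bckdk (camera adjusted p = 0.037, and 0.22 with an estimated correlation). Bckdk encodes the kinase that inhibits the dehydrogenase complex of this pathway, so its rise is no sign of more breakdown. Genes of fatty acid oxidation, prompted by Ehhadh, went the other way, with a median of -0.15, 0 of 19 risen and 3 fallen, Cpt1a, Eci2 and Pex11a (adjusted p = 0.037; adjusted p = 0.22 with an estimated correlation). Hypoxia response genes, prompted by the lower Ldha and Hk2, may be lower as a group, with a median of -0.19, 2 of 14 fallen (Ddit4, P4ha1) and 1 risen, Ero1a (adjusted p = 0.037; adjusted p = 0.22 with an estimated correlation). Estrogen-responsive genes, prompted by Esr1, were not higher, with a median of -0.16, 0 of 10 risen and Igfbp4 fallen (adjusted p = 0.33), and adjusted over the list alone 1 rose (Abca3) and 3 fell. Adjusted over the list alone, 2 rose and 0 fell for branched-chain breakdown, 0 and 3 for fatty acid oxidation and 1 and 3 for hypoxia. None of the 4 holds with an estimated correlation, and 0 had an unadjusted p under 0.05 there.

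A smaller acinar share in the pregnant preparations stays open for the lower acinar markers: all 24 were lower on non-pregnant replicate 2 than on both other non-pregnant arrays, but that array was picked by the median of these same markers, so the count does not decide. The rise of Bhlha15 (1.18 ± 0.09) argues against a smaller share for that gene, and a median of -1.12 with quantile normalization argues against MAS5 scaling. Regulation of acinar genes in pregnancy stays open: 12 of 23 markers still differed once the common acinar median was subtracted, which met the value set beforehand for regulation, but 0 passed (2 at an unadjusted p under 0.05) when each had its own slope on that median, a requirement added after the result was seen. Of the 12, 5 were higher and 7 lower. Subtracting a common median leaves such differences whenever slopes differ, so the 12 alone do not decide. An acinar share as the source of all lower calls is argued against, since 28.7% of 1261 outside the list (Wilson interval 26.3% to 31.3%) had replicate 2 as the lowest non-pregnant array, against 33.3% by chance, 30.6% of all probe sets tested and 40.7% of the higher calls outside the list. For the 87 that were at least 2-fold lower it was 40.2% (30.6% to 50.7%), about the share of the higher calls, which leaves it open, as the interval, asked for after the value was seen, crosses the 50% set beforehand. Both intervals treat probe sets as independent, though all were read on the same arrays, so they understate the uncertainty. Calls also favour a low spread within a group, which can leave out probe sets that drop on replicate 2. The 28.7% thus speaks only against acinar share as the source of every lower call, and a part of them stays open.

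The rise of cell division genes (mitosis median 1.09, DNA replication median 0.59) was weighed against 3 other sources. A lower acinar share that raises all other cells alike is argued against by the beta cell median of 0.002 (SE 0.07). A general rise of endothelial, stellate, macrophage or lymphoid cells as large as the DNA replication median is argued against by those lists' medians. The highest upper bound (median plus 2 SE) was 0.15, for the lymphocyte list with 6 genes tested. These SE treat the genes of a list as independent. The medians cannot exclude a small dividing fraction of such cells, which need not move them. A single array is argued against by the mitosis median of at least 0.94 with any 1 array left out. Division of islet cells in pregnancy is thus a candidate explanation, open and untested for which cells divide.

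The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave each count below. The real groups gave 2587 probe sets past the threshold, 1294 higher, 1293 lower and 311 at least 2-fold, and the highest of the other splits was 1 past the threshold and 1 at least 2-fold. As a split has no set direction, higher and lower were each compared with the larger direction of the other splits, 1 at most. For gene lists the real groups gave 11 calls and the other splits 3 to 8. Every other split mixes pregnant and non-pregnant arrays, so a group difference adds to the spread within its sides and lowers its probe set counts. Those counts thus do not show what arrays without a group difference would give.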
